A study of Homo sapiens with 24 samples.

How the data were processed

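Per the labels' protocols, LUHMES cells were differentiated into neurons of dopaminergic type and exposed for 6 h, RNA was selected for polyadenylated transcripts and passed through 2 rounds of ribosomal RNA depletion, and libraries were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were aligned with STAR to GRCh38, counted per gene with HTSeq and normalized with DESeq; the versions of these tools, the annotation, the strand setting and the handling of reads that map to several genes are not given in the sources used here. The authors deposited a matrix of raw counts and a matrix of normalized signal, each with 58051 genes and 1 column for each of the 24 libraries, and 0 columns were without a sample. The deposited normalized values equalled the counts divided by 1 factor per library, and 100% of them returned to whole counts within a tolerance of 0.01. Genes near-identical in sequence, such as metallothioneins, tubulins, HSP70 genes and mitochondrial RNAs with nuclear copies, may have exchanged or lost reads, and genes that overlap on opposite strands may have shared them. Of the 58051 genes, 56948 matched the name table by identifier. Names and coordinates came from GENCODE 29 (57447 genes), and 266 genes without a name held 0.00492% of the counts.

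The counts were fitted with edgeR, with trimmed mean of M values (TMM) scaling, the default expression filter (18852 genes kept) and 1 coefficient for each of the 8 groups over all 24 libraries, which left 16 residual degrees of freedom. Each toxicant was tested against DMSO, and MPP against paraquat, with the quasi-likelihood F test and Benjamini-Hochberg adjustment per comparison at 0.05. Values are given as CPM, the counts of a gene per megaread of the TMM-scaled library total, with the SD over 3 libraries, and fold changes on the log2 scale with the SE of the fit or a 95% interval. Where a gene had 1 to 3 counts over the 3 DMSO libraries, the ratio of summed counts was given with an exact 95% interval for counting error, and where it had 0 counts, a bound against a floor of 3 counts over the group.

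The groups, comparisons, thresholds, gene lists, naming rule and most alternatives were chosen before the data were examined. The 26 lists were metallothioneins, zinc transporters, NRF2 oxidative stress targets, heat shock (HSF1) targets, integrated stress response (ATF4) targets, endoplasmic reticulum unfolded protein response genes, p53 targets, BH3-only and BAX-like death genes, cholesterol synthesis and uptake (SREBP2) targets, hypoxia (HIF) targets, glycolytic enzymes, mitochondrially encoded proteins, nuclear complex I subunits, immediate early genes, NF-kB and chemokine genes, tubulins, proteasome subunits, cytosolic ribosomal proteins, histone deacetylases, responders to histone deacetylase inhibition, dopaminergic neuron markers, pan-neuronal markers, Parkinson disease genes, cycling cell markers, neural precursor markers, and astrocyte and oligodendrocyte markers. Each list was tested with camera of limma at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over 26 lists and 7 comparisons, and again with the correlation estimated from the data and with the rotation test fry; MPP against paraquat formed its own family. A count adjusted over the list alone repeats the Benjamini-Hochberg adjustment on the members of that list.

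Named genes were, per comparison, up to 10 higher and 10 lower by fold change among genes with an adjusted p under 0.05, at least 2 CPM in the higher group and no overlap between the libraries of the 2 groups, leaving out clone names. Added to these were up to 4 members of each list, all metallothioneins, and up to 10 genes shared by most toxicants. Overlaps between comparisons that share the DMSO libraries were set against 20 simulations of unchanged groups. The same procedure was run on simulated counts for 17620 genes, with the same spread of a gene in all groups and with genes changed by known amounts. At a change of 1 on the log2 scale it recovered from 54% (MS275) to 73.4% (6-HD) of them, at 2 from 75.4% (paraquat) to 90% (rotenone) and at 0.5 from 24.6% (methylmercury) to 32.3% (paraquat and MPP). False calls ranged from 3 of 111 (rotenone) to 7 of 120 (paraquat). The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.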

Results

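RNA sequencing counts were analysed for 24 libraries of neurons differentiated from LUHMES cells, an immortalised line of human mesencephalic precursor cells that can be turned into post-mitotic neurons of dopaminergic type. Cultures received 1% DMSO as the vehicle or 1 of 7 toxicants for 6 h, with 3 libraries in each of the 8 groups. The toxicants were 5 µM MS275 (entinostat, an inhibitor of class I histone deacetylases), 5 µM paraquat, 5 µM MPP (the methylphenylpyridinium ion), 2 µM ziram (a zinc dithiocarbamate fungicide), 1 µM rotenone (an inhibitor of mitochondrial complex I), 1 µM 6-HD (hydroxydopamine, an oxidisable analogue of dopamine) and 0.5 µM methylmercury. Library totals, in megareads counted to genes, ranged from 14.3 to 33.4 in DMSO, 14.4 to 30 in MS275, 15.2 to 45.1 in paraquat and 20.6 to 31.8 in MPP. They ranged from 29.5 to 46.9 in ziram, 9.69 to 24.7 in rotenone, 10.4 to 21.9 in 6-HD and 14.5 to 32.9 in methylmercury. Each toxicant was compared with DMSO by the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment over 18852 genes, whose result is given as the edgeR adjusted p. The libraries were labelled as biological samples in triplicate. The edgeR p-values measure a difference against the spread between these samples, pooled over all 8 groups and not taken from the 2 groups compared. With the 2 groups fitted alone, rotenone called 211 genes instead of 1041 and ziram 586 instead of 100. Gene lists fixed before the data were examined were tested with camera, and the camera adjusted p covers 182 list tests, of which 64 passed with the preset correlation between genes and 10 with an estimated one.

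**Figure D1:**
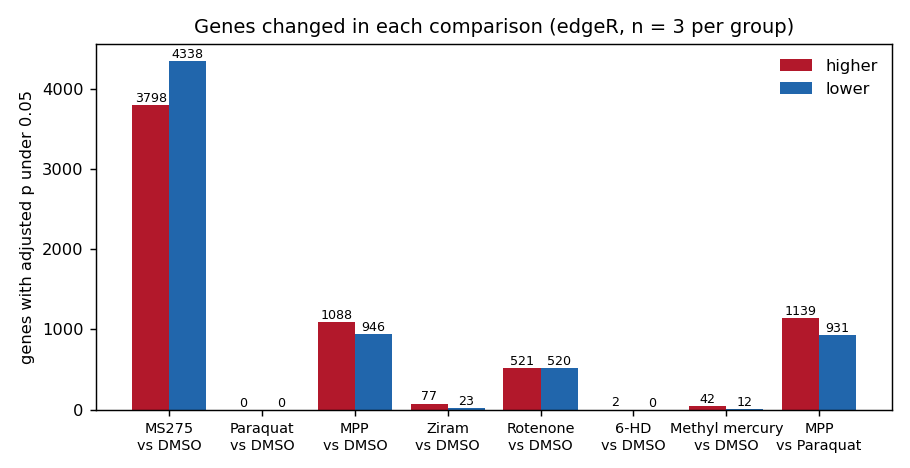
Number of genes with an edgeR adjusted p under 0.05 in each comparison, with genes higher in the first-named group drawn as one bar and genes lower as the other (y axis, number of genes). MS275 called 8136 genes, MPP 2034, rotenone 1041, ziram 100, methylmercury 54, 6-HD 2 and paraquat 0.

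The title of the series names MT1G, a metallothionein that binds zinc and other metals, as a marker of neurotoxicity, so its level was compared first. MT1G (chromosome 16, 56666731 to 56668065, GRCh38) was close to absent in DMSO, with 0, 1 and 1 reads in the 3 libraries and a mean of 0.0233 ± 0.0209 CPM (SD, n = 3). It reached 532 ± 74.9 CPM in ziram, 19300 times the DMSO level by counts (exact 95% counting interval 5360 to 160000), with an edgeR adjusted p of 2.62e-10. In rotenone MT1G stood at 7.04 ± 9.91 CPM, 376 times DMSO (103 to 3110), with an edgeR adjusted p of 0.00115, but 457 of its 486 reads came from rotenone replicate 1. Without that library its edgeR adjusted p was 0.118. In MPP it stood at 2.35 ± 0.925 CPM, 75.2 times DMSO (20.5 to 626), with an edgeR adjusted p of 0.0404. Leaving out any 1 library ended that call, with an edgeR adjusted p of 0.0996, 0.114 or 0.14 without DMSO replicate 1, 2 or 3 and of 0.0503, 0.0775 or 0.0973 without MPP replicate 1, 2 or 3. Methylmercury held 3.17 ± 0.354 CPM of MT1G, 113 times DMSO (30.9 to 938), which did not pass over all genes (edgeR adjusted p = 0.12).

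MT1G was not called in the other 3 groups, whose libraries differed widely among themselves. The 3 MS275 libraries held 0, 55 and 27 MT1G reads (edgeR adjusted p = 0.0686, and 0.0306 without MS275 replicate 1), the paraquat libraries 32, 0 and 50 (edgeR adjusted p = 1) and the 6-HD libraries 0, 5 and 59 (edgeR adjusted p = 0.851). In the 15 libraries of MS275, paraquat, MPP, rotenone and 6-HD together, MT1G gave 884 reads, against 57063 in the 3 ziram libraries. For each MT1G read, those 15 libraries held MT1E, MT2A and MT1M above their DMSO level at 0.979, 1.03 and 1.02 times the proportions found in ziram, while MT1X stood at 0.235 (95% interval -0.484 to 0.954) and MT1F at -0.706 (-3.11 to 1.7) times them, both with a higher level in DMSO. Exact counting intervals, here and elsewhere, cover counting error only, because the reads carried no stated molecular identifiers. The 95% intervals of MT1X and MT1F also take in the spread between the DMSO libraries. Metallothionein genes are near-identical copies, so the split of reads among them is uncertain.

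**Figure D2:**
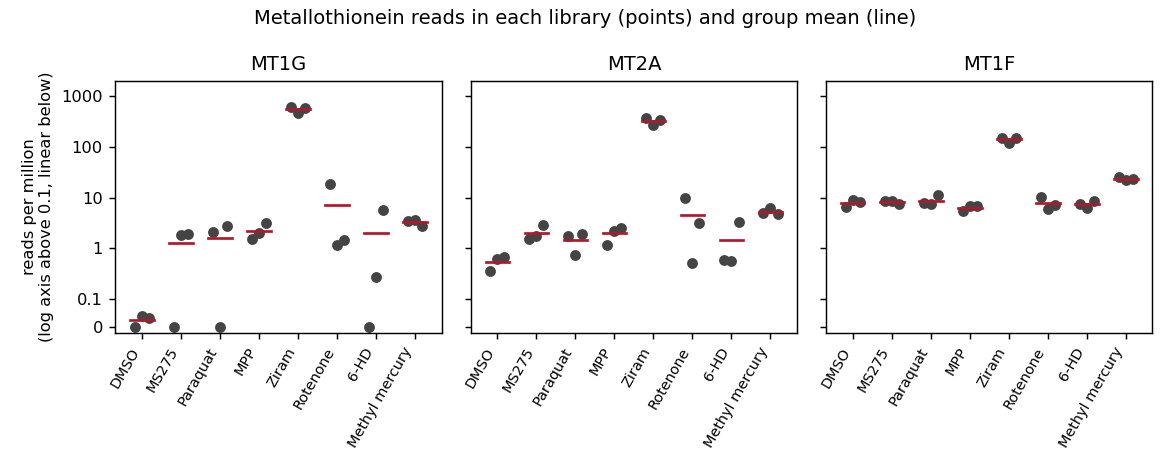
MT1G, MT2A and MT1F in reads per megaread of the library total, without TMM scaling (y axis, logarithmic above 0.1 and linear below), for every library of the 8 groups (x axis). Each point is a library and each bar the group mean. The 3 ziram libraries stand above all others for each gene. With TMM scaling, which is not drawn here, MT1G averaged 532 CPM in ziram and 0.0233 CPM in DMSO.

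MS275 raised SUSD3 80.4-fold, from 0.124 ± 0.145 CPM in DMSO to 11.4 ± 1.91 CPM (SD, n = 3 each; log2 fold change 6.33 ± 0.72 SE; edgeR adjusted p = 2.93e-08). It raised ARSI, which encodes a sulfatase, 60.4-fold and RASD2, a small GTPase enriched in striatum, 36.8-fold, while HS3ST6, a heparan sulfate sulfotransferase with 0 reads in DMSO, was at least 95.2-fold higher against a floor of 3 counts over the group. UNG (chromosome 12, 109097574 to 109110992), the uracil DNA glycosylase of base excision repair, fell to 0.244 of its DMSO level, from 51.3 ± 1.38 to 12.4 ± 1.21 CPM (edgeR adjusted p = 3.01e-14). CDC25A, a phosphatase that drives entry into S phase, fell to 0.249, PIK3IP1, an inhibitor of phosphatidylinositol kinase, to 0.246, and NAGPA, which uncovers the mannose phosphate tag of lysosomal enzymes, to 0.0932. In all, 3798 genes were higher and 4338 lower, 8136 of the 18852 tested. The larger side turned with the settings, to 4253 higher and 3783 lower with RLE size factors, 4527 and 3918 with DESeq2 and 4780 and 4245 with the 2 groups fitted alone. Of the 8136 genes, 2462 changed at least 2-fold, 2010 upwards and 452 downwards.

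Among genes known to respond to inhibition of histone deacetylases, 4 of 5 rose under MS275 and 0 fell, also 4 when adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.297 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, rose 2.49-fold and DHRS2, a short-chain dehydrogenase, 7.65-fold. Of 21 markers of cycling cells, 15 fell and 0 rose (16 and 1 adjusted over the list alone, camera adjusted p = 1.99e-05; adjusted p = 0.226 with an estimated correlation), including the replicative helicase subunits MCM4, MCM5 and MCM7 at 0.536, 0.467 and 0.533 of DMSO and the mitotic kinase AURKA at 0.378. Of 31 proteasome subunits, 24 fell and 0 rose (25 and 0 adjusted over the list alone, camera adjusted p = 2.58e-06; adjusted p = 0.0896 with an estimated correlation), among them the ATPase subunit PSMC2, which fell to 0.598. Of 19 heat shock genes, 10 fell and 4 rose (11 and 5 adjusted over the list alone, camera adjusted p = 0.0294; adjusted p = 0.494 with an estimated correlation). The co-chaperone DNAJB1 fell to 0.451, whereas BAG3, which couples chaperones to autophagy, rose by 1.12 on the log2 scale. Of 18 genes of the endoplasmic reticulum unfolded protein response, 9 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00744; adjusted p = 0.316 with an estimated correlation), led by the luminal chaperone HSPA5 at 2.24-fold. Among the deacetylases themselves, 4 of 11 rose and 1 fell, HDAC9 rising 2.3-fold, and the list as a whole was not called (camera adjusted p = 0.287).

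Some lists of cell type markers also moved under MS275, while of 23 pan-neuronal markers 5 rose, 1 fell and 17 were not called, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.468). Of 16 markers of dopaminergic neurons, 10 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0256; adjusted p = 0.285 with an estimated correlation). The transcription factor NR4A2 rose 2.69-fold, and the dopamine transporter SLC6A3 rose by 0.67 on the log2 scale, from 636 to 1010 CPM. Of 11 markers of neural precursors, 7 rose and 0 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.00817; adjusted p = 0.113 with an estimated correlation), with SOX1 up by 2.03 and the Notch effector HES1 by 1.58 on the log2 scale. Of 12 markers of astrocytes and oligodendrocytes, 10 of which were at 1 CPM or more in DMSO, 8 rose and 1 fell, as they did adjusted over the list alone (camera adjusted p = 0.0443; adjusted p = 0.151 with an estimated correlation; camera adjusted p = 0.0544 without DMSO replicate 1). ALDH1L1 rose by 2.93 and SOX9 by 1.99 on the log2 scale. Of 37 nuclear subunits of complex I, 13 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 0.0487; adjusted p = 0.682 with an estimated correlation). That call was lost without DMSO replicate 1 (camera adjusted p = 0.0883) and without MS275 replicate 3 (0.263), with RLE size factors (0.0821) and with the replicate number as a block (0.0539).

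Paraquat, a redox-cycling herbicide, moved no single gene past the threshold. The genes nearest to a change by list were targets of the hypoxia-inducible factor. PDK1, the kinase that restrains pyruvate dehydrogenase, stood at 47.1 CPM against 66.1 CPM in DMSO, a log2 difference of -0.50 ± 0.14 (95% interval -0.77 to -0.22). The glucose transporter SLC2A1 differed by -0.32 (-0.53 to -0.10) and the mitophagy receptor BNIP3 by -0.30 (-0.54 to -0.07). Of the 20 hypoxia genes tested 0 passed over all genes and 4 fell when adjusted over the list alone, and the list was lower as a group (median log2 fold change -0.24; camera adjusted p = 1.6e-19; adjusted p = 0.0279 with an estimated correlation), though the rotation test fry gave an adjusted p of 0.0519. The mean difference of the list, -0.25, became -0.10 without DMSO replicate 3, whose hypoxia mean of 0.31 stood above -0.178 and -0.132 in the other DMSO libraries, and -0.39 without paraquat replicate 3 (0.025). Of 17 glycolytic enzymes 0 were called, over all genes or over the list alone, and camera placed the list lower (adjusted p = 0.0146; adjusted p = 0.641 with an estimated correlation), a call lost without DMSO replicate 1 (0.27) or paraquat replicate 2 (0.793). Of 27 NRF2 targets 0 were called, over all genes or over the list alone, and camera placed the list higher (adjusted p = 0.00817; adjusted p = 0.151 with an estimated correlation), a call lost without DMSO replicate 3 (0.333) or paraquat replicate 1 (0.112) or 3 (0.0842). Of 9 metallothioneins 0 were called either way, with the list placed higher (camera adjusted p = 0.0293, adjusted p = 0.638 with an estimated correlation), a call lost without DMSO replicate 3 (0.127) or paraquat replicate 1 (0.0524) or 3 (0.498). Markers of cycling cells (camera adjusted p = 0.00497, lower, and 0.443 with an estimated correlation), ribosomal proteins (0.00577, higher, and 0.724) and Parkinson disease genes (0.0372, lower, and 0.297) also passed only with the preset correlation, with 0 members called. The first was lost without DMSO replicate 3 (0.189) or paraquat replicate 3 (0.521), the ribosomal call without DMSO replicate 2 (0.153) or 3 (0.371), and the last without DMSO replicate 1 (0.0883) or 2 (0.41) or paraquat replicate 1 (0.173) or 2 (0.447). The call of Parkinson disease genes was also lost with the replicate number as a block (camera adjusted p = 0.0504). edgeR called 0 of 18852 genes in paraquat, with 182 at an unadjusted p under 0.05 where chance gives 943, and DESeq2 and limma-voom called 0. In counts simulated at the depth of these libraries, the same test recovered 73% of genes changed by 1 on the log2 scale and 32.3% of those changed by 0.5 (17620 genes). That simulation gave each gene the same spread in all groups, so it does not cover groups that differ in spread.

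MPP, the active metabolite of the dopaminergic toxin MPTP, raised both mitochondrial ribosomal RNAs, MT-RNR2 (mitochondrial genome, 1671 to 3229) by 4.66-fold, from 11100 ± 2910 to 51700 ± 13100 CPM (edgeR adjusted p = 3.23e-10), and MT-RNR1 by 4.65-fold. They made up 5.47 ± 1.25% of all counts in MPP and 1.25 ± 0.296% in DMSO (SD, n = 3 each). ELFN2 (chromosome 22, 37367960 to 37427470), a leucine-rich repeat protein of neuronal synapses, rose 16.7-fold, from 1.13 ± 0.319 to 19.7 ± 4.89 CPM (log2 fold change 4.06 ± 0.27 SE; edgeR adjusted p = 6.43e-12). The receptor PEAR1 rose 8.57-fold and the cystine transporter SLC7A11 4.34-fold. TXNIP (chromosome 1, 145992435 to 145996600), which inhibits thioredoxin and glucose uptake, fell to 0.301, from 123 ± 6.91 to 37 ± 6.07 CPM (edgeR adjusted p = 2.43e-12). TH, the rate-limiting enzyme of dopamine synthesis, fell to 0.625, from 50.8 ± 4.7 to 31.7 ± 1.45 CPM (edgeR adjusted p = 0.00087), but of the 16 dopaminergic markers tested 1 rose, 2 fell and 13 were not called, the same adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.808).

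In all, MPP changed 2034 genes, 1088 higher and 946 lower, of which 91 rose and 206 fell at least 2-fold. Of 13 proteins encoded in mitochondria, 9 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.81e-05; adjusted p = 0.329 with an estimated correlation). Together these 13 genes held a lower share of all counts in MPP, 0.23 ± 0.0315% against 0.29 ± 0.0095% in DMSO (SD, n = 3 each). MT-ND1 and MT-ND4L, subunits of complex I, rose 3.26-fold and 4.13-fold, while MT-CO1 and MT-CO3, subunits of cytochrome c oxidase, fell to 0.722 and 0.595 and MT-ND3 to 0.447. These directions were the same under size factors of the RLE kind and under library totals. Of 18 genes of the endoplasmic reticulum unfolded protein response, 10 fell and 0 rose (11 and 1 adjusted over the list alone, camera adjusted p = 1.45e-09; adjusted p = 0.0242 with an estimated correlation), with the co-chaperones SDF2L1 at 0.395 and DNAJC3 at 0.53 of DMSO. Of 35 targets of ATF4 in the integrated stress response, 12 rose and 2 fell (14 and 3 adjusted over the list alone, camera adjusted p = 1.05e-05; adjusted p = 0.0954 with an estimated correlation). CHAC1, which degrades glutathione, rose 3.1-fold, the transcription factor DDIT3 2.72-fold and ATF4 itself 1.48-fold. Of 23 p53 targets, 6 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0102; adjusted p = 0.131 with an estimated correlation), with CCNG1 up by 0.57 and the death receptor TNFRSF10B by 0.52 on the log2 scale.

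Among 12 tubulins under MPP, 3 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.00271; adjusted p = 0.329 with an estimated correlation), and TUBA1A fell by 0.41 on the log2 scale. Among 20 hypoxia genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.000233; adjusted p = 0.413 with an estimated correlation; camera adjusted p = 0.052 without DMSO replicate 3), with PDK1 at a log2 fold change of -0.73. The mean difference of the hypoxia list, -0.27, became -0.11 without DMSO replicate 3. Without normalization beyond library totals, 592 genes were higher and 1564 lower, so that 27.5% of calls were higher instead of 53.5%. The count of calls fell to 1212 without DMSO replicate 1, 1186 without DMSO replicate 2 and 1142 without MPP replicate 2.

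**Figure D3:**
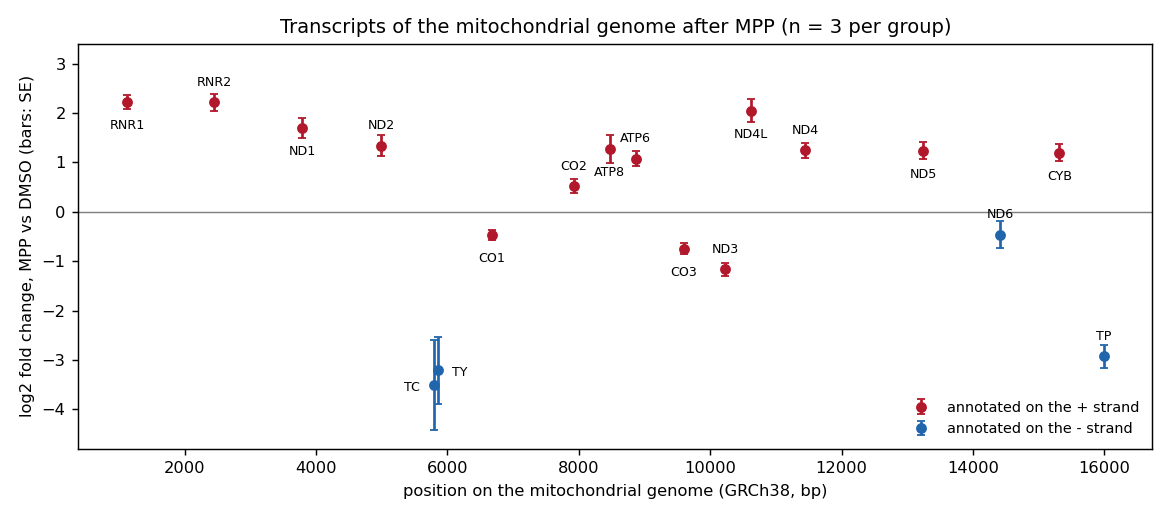
Log2 fold change of mitochondrial genes in MPP against DMSO (y axis, bars are ± 1 SE) by position on the mitochondrial genome in bases (x axis), with genes of the 2 strands drawn in different colours. MT-RNR1 and MT-RNR2 stand at 2.22, MT-CO3 at -0.75 and MT-ND3 at -1.16, with the same signs under every scaling tried.

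MPP and paraquat are both pyridinium cations, given here at the same dose of 5 µM for the same 6 h; MPP holds 1 pyridinium ring with a phenyl group and paraquat is a bipyridinium with 2 charged rings. ELFN2 was 14-fold higher in MPP than in paraquat (log2 difference 3.80 ± 0.26 SE; edgeR adjusted p = 3.66e-11), PEAR1 9.81-fold, MT-RNR1 4.37-fold and SLC7A11 3.59-fold. TXNIP stood at 0.356 of its paraquat level (edgeR adjusted p = 3.9e-11) and TH at 0.568, with 31.7 ± 1.45 CPM in MPP and 56 ± 7.38 CPM in paraquat (edgeR adjusted p = 0.000105). Tested directly, 2070 genes differed between the 2 compounds, 1139 higher and 931 lower in MPP. Of 18 genes of the unfolded protein response, 11 were lower in MPP and 0 higher (12 and 0 adjusted over the list alone, camera adjusted p = 4.52e-09; adjusted p = 0.0314 with an estimated correlation), and of 35 ATF4 targets 10 were higher and 1 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.000209; adjusted p = 0.249 with an estimated correlation). DDIT3 was 2.31-fold and CHAC1 2.39-fold higher in MPP.

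No difference was detected between MPP and paraquat for MT1G, where the log2 difference was 0.95 with a 95% interval of -0.98 to 2.87 (edgeR adjusted p = 0.599). Nor was one detected for the 20 hypoxia genes, of which 0 were called in either direction, over all genes or over the list alone (camera adjusted p = 0.788). With library totals alone, 579 genes were higher and 1608 lower in MPP, so that 26.5% of calls were higher instead of 55%. The count of calls fell to 1237, 1324 and 1268 without paraquat replicate 1, 2 and 3, and to 1157 and 1332 without MPP replicate 2 and 3.

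Ziram raised every metallothionein that could be tested and few other genes by as much. MT2A (chromosome 16, 56608199 to 56609497) rose 548-fold, from 0.537 ± 0.159 to 318 ± 49.1 CPM (log2 fold change 9.10 ± 0.48 SE; edgeR adjusted p = 1.99e-14), MT1X 67.6-fold and MT1F 17.1-fold. MT1M, MT1H, MT1L and MT1A, with 0 reads in DMSO, were at least 2030, 213, 208 and 32.5 times higher against a floor of 3 counts over the group. All 9 metallothioneins rose, also when adjusted over the list alone, with a median fitted log2 fold change of 10.73, or 7.73 with the 4 genes absent from DMSO set at their bound (camera adjusted p = 1.39e-53; adjusted p = 0.000375 with an estimated correlation). That list was chosen because the series title names MT1G and is not independent evidence. Of its 12 members 9 were tested, and MT1H, MT1L and MT1A passed the expression filter only through their reads in ziram. The call of MT1A was lost without DMSO replicate 1, 2 or 3 (edgeR adjusted p = 0.0543, 0.083 and 0.0872) and without ziram replicate 1 (0.0699). The zinc exporters SLC30A1 (chromosome 1, 211571568 to 211578742) and SLC30A2 rose 3.52-fold and 20-fold, and the zinc importer SLC39A10 (chromosome 2, 195575977 to 195737702) fell to 0.559, from 282 to 157 CPM (edgeR adjusted p = 1.64e-07). In the list of 21 zinc transporters 2 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.916).

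HMOX1 (chromosome 22, 35380361 to 35394214), the heme oxygenase, rose 7.27-fold in ziram, from 24.8 ± 1.07 to 180 ± 63.5 CPM (edgeR adjusted p = 3.54e-13), SLC7A11 10.3-fold and the malic enzyme ME1 2.8-fold. Of 27 NRF2 targets of the oxidative stress response, 5 rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 2.1e-06; adjusted p = 0.0139 with an estimated correlation). Of 19 heat shock genes, 7 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 1.17e-30; adjusted p = 0.000375 with an estimated correlation). HSPH1, a nucleotide exchange factor for HSP70, rose 1.91-fold, and HSPA6, an inducible HSP70 with 3 reads in DMSO, stood at 235 times its DMSO level (exact 95% counting interval 80.3 to 1140). Of 35 ATF4 targets, 12 rose and 0 fell (27 and 0 adjusted over the list alone, camera adjusted p = 5.33e-46; adjusted p = 2.27e-05 with an estimated correlation), with the secreted glycoprotein STC2 at 3.02-fold. Of 20 hypoxia genes, 2 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 8.23e-15; adjusted p = 0.0632 with an estimated correlation). Of 17 immediate early genes, 2 rose and 0 fell, also over the list alone (camera adjusted p = 0.0104; adjusted p = 0.113 with an estimated correlation), a call lost without DMSO replicate 1 (0.0678) or ziram replicate 1 (0.0962). The neurotrophic factor NDNF fell to 0.361 and the adhesion molecule ALCAM to 0.64. In all, ziram changed 100 genes, 77 higher and 23 lower, or 102 higher and 13 lower (88.7% instead of 77% higher) with library totals alone. The count fell to 58 without DMSO replicate 1, 42 without DMSO replicate 2 and 40 without ziram replicate 1.

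Rotenone, which besides complex I also binds tubulin, lowered tubulin transcripts. TUBA1A (chromosome 12, 49184796 to 49189324), the main neuronal alpha tubulin, fell to 0.31 of its DMSO level, from 11200 ± 453 to 3480 ± 326 CPM (log2 fold change -1.69 ± 0.08 SE; edgeR adjusted p = 9.48e-16), TUBB2A to 0.323, TUBB4B to 0.371 and TUBB4A to 0.291. Of 12 tubulins tested, 11 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 4.19e-32; adjusted p = 0.000375 with an estimated correlation). Tubulin genes are close copies of one another, so the split of reads among them is uncertain. HRK (chromosome 12, 116856144 to 116881441), a BH3-only promoter of neuronal death, rose 4.4-fold, from 27.1 ± 2.36 to 119 ± 4.33 CPM (edgeR adjusted p = 2.6e-13). ELFN2 rose 4.38-fold, the transcription factor CREB5 3.39-fold, and the clock repressor CIART fell to 0.308. The immediate early factor JUN rose by 0.80 on the log2 scale.

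Of 20 hypoxia genes under rotenone, 6 fell and 0 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.000202; adjusted p = 0.413 with an estimated correlation), with SLC2A1 at a log2 fold change of -0.70. The mean difference of that list, -0.39, became -0.23 without DMSO replicate 3. Of 52 cytosolic ribosomal proteins, 8 rose and 0 fell (26 and 0 adjusted over the list alone, camera adjusted p = 2.03e-16; adjusted p = 0.317 with an estimated correlation), with RPL7 up by 0.38 on the log2 scale. This list passed camera in all 7 comparisons with DMSO, though as lower in ziram (camera adjusted p = 1.91e-13), and in 0 of them with an estimated correlation. Of 35 ATF4 targets, 6 fell and 2 rose (10 and 3 adjusted over the list alone, camera adjusted p = 0.00654; adjusted p = 0.316 with an estimated correlation), with DDIT4, an inhibitor of mTOR signalling, at 0.399. Of 9 metallothioneins, 4 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00147; adjusted p = 0.474 with an estimated correlation). Both of these list calls were lost without rotenone replicate 1, with a camera adjusted p of 0.119 for the ATF4 targets and 0.183 for the metallothioneins. The dopamine transporter SLC6A3 rose by 0.72 on the log2 scale, from 636 ± 59.9 to 1050 ± 182 CPM. Of the 16 dopaminergic markers tested, however, 1 rose, 1 fell and 14 were not called (1 and 2 adjusted over the list alone). The list as a whole was not called (camera adjusted p = 0.603). In all, rotenone changed 1041 genes, 521 higher and 520 lower. The count was 599, 483 and 537 without DMSO replicate 1, 2 and 3, and 1616 without rotenone replicate 1, whose deviation from its group (0.56, root mean square on the log2 scale) was among the largest.

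The transcripts raised by 6-HD encode proteins of the endoplasmic reticulum. HSPA5 (chromosome 9, 125234853 to 125241330), its main chaperone, rose 1.66-fold, from 110 ± 12.1 to 183 ± 31.5 CPM (log2 fold change 0.73 ± 0.13 SE; edgeR adjusted p = 0.0392), and MANF (chromosome 3, 51385047 to 51389397), a secreted factor that protects dopaminergic neurons, rose 1.55-fold, from 77.2 ± 6.18 to 120 ± 21.7 CPM (edgeR adjusted p = 0.0392). For both, the 3 libraries of 6-HD lay apart from the 3 of DMSO without overlap, which chance gives in 10% of genes when either direction is counted. They were the 2 genes called among 18852, and 0 fell. Of 18 genes of the unfolded protein response, these 2 rose over all genes and 12 when adjusted over the list alone, with 0 lower (camera adjusted p = 3.18e-22; adjusted p = 0.000505 with an estimated correlation). Of 21 markers of cycling cells 0 passed, over all genes or over the list alone, and camera placed the list higher (median log2 fold change 0.21; camera adjusted p = 4.28e-09; adjusted p = 0.0896 with an estimated correlation).

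Both single-gene calls in 6-HD held without 6-HD replicate 2 and were lost without several other libraries. HSPA5 was lost without 6-HD replicate 1 or 3 (edgeR adjusted p = 0.225 and 0.0675) and without DMSO replicate 1, 2 or 3 (0.478, 0.322 and 0.0931), and MANF was lost without 6-HD replicate 3 (0.281) and without DMSO replicate 1, 2 or 3 (0.0785, 0.441 and 0.203). The count of calls in 6-HD was 0 without any 1 DMSO replicate, 1 without 6-HD replicate 1 or 3 and 6 without the furthest library of rotenone, 6-HD and methylmercury, and DESeq2 called 8. With the replicate number as a block, and with a limma trend fit on the normalized values, the count was 0.

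Methylmercury, an electrophilic organomercurial, raised NQO1 (chromosome 16, 69706996 to 69726951), a quinone reductase, 2.89-fold, from 28.8 ± 2.47 to 83.6 ± 6.54 CPM (log2 fold change 1.53 ± 0.13 SE; edgeR adjusted p = 1.32e-08). HMOX1 rose 3.01-fold (edgeR adjusted p = 7.24e-07), the zinc exporter SLC30A1 2.78-fold, MT1F 2.93-fold and the selenoprotein TXNRD1, which reduces thioredoxin, 1.52-fold. Of 27 NRF2 targets, 5 rose and 0 fell (10 and 1 adjusted over the list alone, camera adjusted p = 3.74e-11; adjusted p = 0.000842 with an estimated correlation). Of 9 metallothioneins, 4 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 1.11e-07; adjusted p = 0.194 with an estimated correlation). MT2A rose 8.77-fold (edgeR adjusted p = 0.00778, and 0.0753 without DMSO replicate 2).

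Of 21 markers of cycling cells under methylmercury, 3 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 2.26e-11; adjusted p = 0.0586 with an estimated correlation). Of 19 heat shock genes, 1 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 7.28e-06; adjusted p = 0.131 with an estimated correlation). Of 25 genes of cholesterol synthesis and uptake, 0 passed over all genes, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00044; adjusted p = 0.112 with an estimated correlation; camera adjusted p = 0.0504 without methylmercury replicate 3). In all, methylmercury changed 54 genes, 42 higher and 12 lower, while DESeq2 called 310. The count was 20, 7 and 33 without DMSO replicate 1, 2 and 3, 7 without methylmercury replicate 2 and 170 without methylmercury replicate 3.

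**Figure D4:**
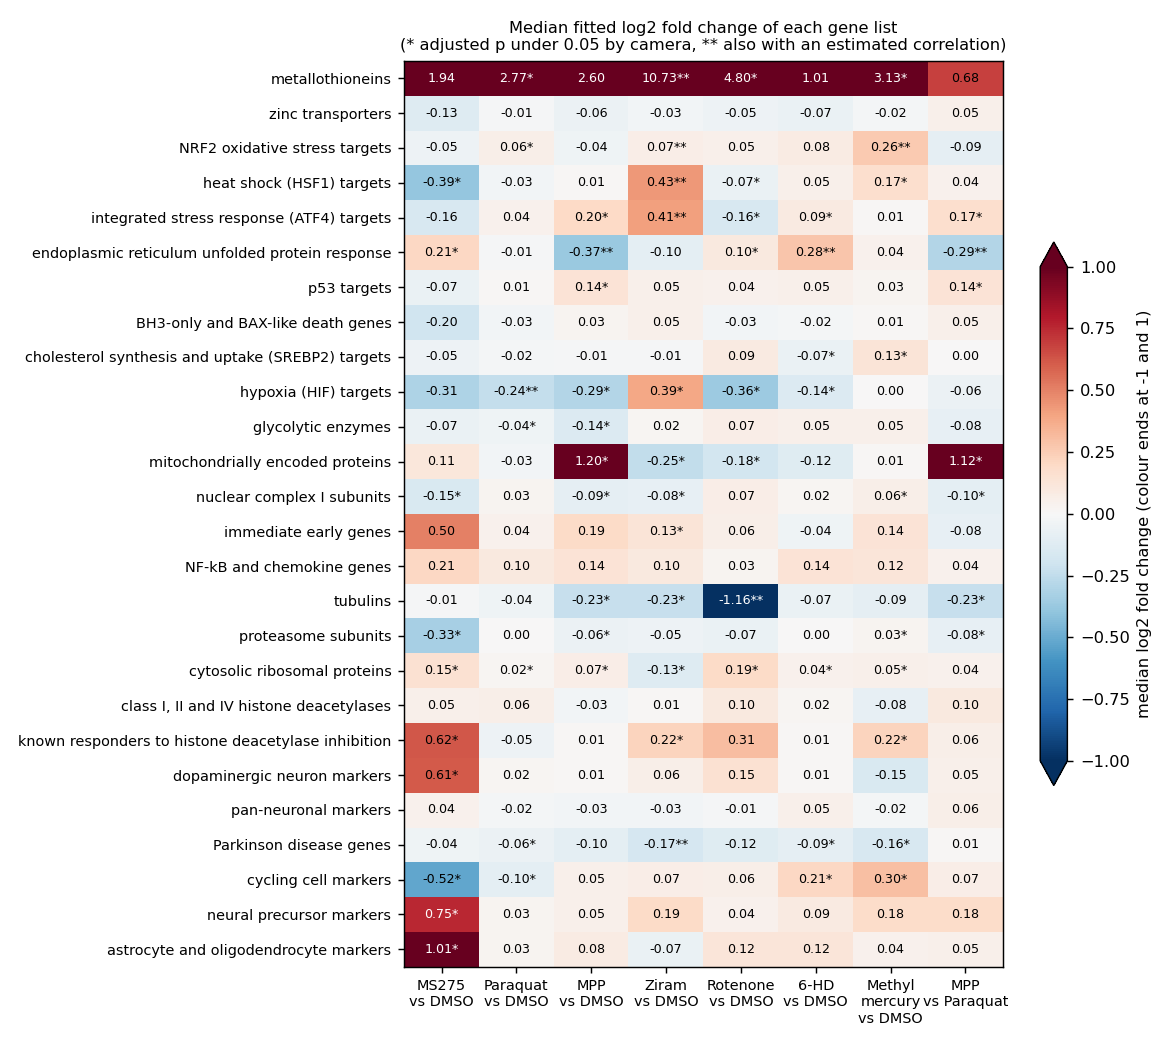
Median fitted log2 fold change of the 26 gene lists (y axis) in each of the 8 comparisons (x axis), with colours ending at -1 and 1; 1 star marks a camera adjusted p under 0.05 and 2 stars a pass with an estimated correlation as well. Tubulins in rotenone and metallothioneins in ziram are among the 2-star lists, with camera adjusted p of 4.19e-32 and 1.39e-53.

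Several genes were called with the same sign in more than 1 toxicant. ELFN2 was higher in MS275, MPP, ziram and rotenone, at 12.3-fold, 16.7-fold, 2.6-fold and 4.38-fold. MTURN, which takes part in neuronal differentiation, was lower in the same 4, at 0.672, 0.727, 0.747 and 0.723 of DMSO. The calls in ziram were lost for ELFN2 without DMSO replicate 1 or 2 (edgeR adjusted p = 0.0692 and 0.0825) and without ziram replicate 1 (0.141), and for MTURN without DMSO replicate 1 or 2 (0.0993 and 0.0804) and without ziram replicate 1 or 2 (0.198 and 0.0524). In all, 242 genes were called with 1 sign in at least 3 of the 7 toxicants, 150 higher and 92 lower, 8 in at least 4 and 0 in at least 5. The count of 242 became 128, 115 and 136 without DMSO replicate 1, 2 and 3.

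Rotenone and MPP shared 483 calls of the same sign, 282 higher and 201 lower, with 5 of opposite sign, where independent lists of those sizes would share 30.1 and 26.1. The count of 483 became 265, 234 and 266 without DMSO replicate 1, 2 and 3. Ziram and methylmercury shared 9 genes, all higher: PIR, HMOX1, MT2A, SLC30A2, MT1E, SLC30A1, NQO1, MT1X and MT1F, where independent lists would share 0.172 higher and 0.0146 lower. The count of 9 became 4 and 5 without DMSO replicate 2 and 3 and 5 without methylmercury replicate 2. MPP and paraquat shared 0 genes, as paraquat called 0. All toxicants were compared with the same 3 DMSO libraries, which cannot be split into groups of 2, so part of any excess may come from the shared controls. In 20 simulations of unchanged groups against these controls, 0 calls were shared in any pair and 0 in at least 3 toxicants, but groups without effects give few calls to share, so these values do not measure what the shared controls add to the counts of 483, 9 and 242. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.34 for rotenone and MPP (simulated 0.47; covariance 0.171, simulated 0.116), 0.49 for ziram and methylmercury (simulated 0.53; covariance 0.128, simulated 0.117) and 0.34 for MPP and paraquat (simulated 0.51; covariance 0.0907, simulated 0.116).

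Of the 26 lists, 5 passed camera in none of the 7 comparisons with DMSO when all 24 libraries were fitted with TMM scaling. Their lowest camera adjusted p was 0.0666 for zinc transporters in 6-HD, 0.0523 for BH3-only and BAX-like death genes in ziram, 0.314 for NF-kB and chemokine genes in 6-HD, 0.287 for histone deacetylases in MS275 and 0.082 for pan-neuronal markers in ziram. The death genes passed camera in ziram with RLE size factors (adjusted p = 0.0497), without DMSO replicate 2 (0.0404) and without ziram replicate 2 (0.044). The pan-neuronal markers passed in ziram without DMSO replicate 3 (camera adjusted p = 0.00808) or ziram replicate 3 (0.0296), in paraquat without DMSO replicate 3 (0.0352) or paraquat replicate 3 (0.0387) and in 6-HD without DMSO replicate 1 (0.043). By the rotation test fry, the death genes passed in ziram (adjusted p = 0.0204) and rotenone (0.0205) and the deacetylases in MS275 (0.000182). Single members did pass, such as HRK in rotenone and SLC30A1 in ziram and methylmercury.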

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

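Leaving out the library furthest from its group in rotenone (replicate 1), 6-HD (replicate 3) and methylmercury (replicate 2), with deviations of 0.56, 0.586 and 0.422, and reading counts back from the normalized matrix were tests chosen after the result was seen. Counts read back gave the same numbers of calls. A count of genes is treated as moved when it differs by more than 1.5 times, and where the setting itself does not show why, the cause was not tested. None of the 431 named gene calls reversed direction under the settings tried. None of the 208 list results did so with an adjusted p under 0.05, but the list tests were not run with library totals. Other calls were not followed gene by gene, and the larger side of the calls turned with some settings. It turned in MS275 with RLE size factors (4253 higher, 3783 lower), DESeq2 (4527 and 3918) and the 2 groups alone (4780 and 4245). With library totals it turned in MPP (592 and 1564), in MPP against paraquat (579 and 1608) and in rotenone (466 and 568), and in rotenone also without mitochondrial genes (516 and 526). Size factors of the RLE kind, library totals, a filter on CPM, leaving out mitochondrial genes and limma-voom moved no count of calls that far, and a limma trend fit on the normalized values moved only that of 6-HD, to 0.

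A stricter requirement lowers counts by construction. At a change of at least 2-fold, the calls were 2462 in MS275, 297 in MPP, 39 in ziram, 183 in rotenone, 0 in 6-HD, 12 in methylmercury and 282 in MPP against paraquat, with 37 shared by rotenone and MPP and 20 called in at least 3 toxicants. At an adjusted p under 0.01 they were 1005 in MPP, 54 in ziram, 419 in rotenone, 0 in 6-HD, 15 in methylmercury and 971 in MPP against paraquat, with 204 shared by rotenone and MPP and 97 in at least 3 toxicants.

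Without the expression filter, the calls were 3 in paraquat (MT1G among them), 160 in ziram, 18 in 6-HD and 249 in methylmercury, with 30 shared by ziram and methylmercury and 3 by MPP and paraquat. With the 2 groups of each comparison fitted alone, they were 3983 in MPP, 586 in ziram, 211 in rotenone, 1 in 6-HD and 3541 in MPP against paraquat. DESeq2 called 184 in ziram, 8 in 6-HD and 310 in methylmercury, with 24 shared by ziram and methylmercury and 405 in at least 3 toxicants. Without the furthest 3 libraries, the calls were 3355 in MPP, 203 in ziram, 2260 in rotenone, 6 in 6-HD, 29 in methylmercury and 3376 in MPP against paraquat, with 863 shared by rotenone and MPP and 453 in at least 3 toxicants.

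The fitted log2 fold change of MT1G depends on the prior count, since DMSO held 2 reads. Against 5.19 in MS275 (edgeR adjusted p = 0.0686), 5.16 in paraquat (1), 6.11 in MPP (0.0404), 8.03 in rotenone (0.00115), 5.37 in 6-HD (0.851) and 6.58 in methylmercury (0.12), MT1G passed without the expression filter in MS275 (5.16, edgeR adjusted p = 2.03e-21), paraquat (5.17, 6.29e-17), 6-HD (5.37, 2.29e-18) and methylmercury (6.57, 1.66e-57). The MT1G reads were 0, 55 and 27 in MS275, 32, 0 and 50 in paraquat and 0, 5 and 59 in 6-HD. Unfiltered p-values this small do not reflect that spread between libraries, so they are not evidence of a rise in these groups. MT1G also passed in methylmercury with the 2 groups alone (6.61, edgeR adjusted p = 8.31e-06), in MS275 and methylmercury with DESeq2 (5.57, adjusted p = 0.0103; 6.90, 0.023) and in both without the furthest 3 libraries (5.21, edgeR adjusted p = 0.00432; 6.54, 0.0117). With limma-voom the MT1G calls were lost in MPP (5.53, adjusted p = 0.198) and rotenone (6.87, 0.145).

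Leaving out 1 library at a time gave fitted MT1G values of 4.47 to 5.83 in MS275, 4.17 to 6.21 in paraquat, 5.81 to 6.44 in MPP, 13.73 to 14.32 in ziram, 5.36 to 8.46 in rotenone, 1.98 to 6.20 in 6-HD and 6.31 to 6.91 in methylmercury. The counts of calls ranged from 6795 to 7953 in MS275, 0 to 0 in paraquat, 1142 to 1430 in MPP, 40 to 74 in ziram, 483 to 1616 in rotenone, 0 to 2 in 6-HD, 7 to 170 in methylmercury and 1157 to 1476 in MPP against paraquat. Shared calls ranged from 234 to 610 for rotenone and MPP, 4 to 11 for ziram and methylmercury, 0 to 0 for MPP and paraquat and 115 to 339 for at least 3 toxicants.

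The replicate numbers did not pair the libraries: of 84 pairs with the same number 8 correlated above 0.1 (range -0.313 to 0.296), and 3 of 24 libraries matched their own number best. With the number as a block, 6-HD called 0 genes, and the block moved no other count of calls by 1.5 times. Of 431 named gene calls 283 held under every setting; over 7306 alternatives 6651 kept and 655 lost the call, 478 of these on leaving out 1 library. Of 208 list results 71 were called and 113 held under every setting; over 2288 alternatives 2052 were the same, 178 lost and 58 gained a call, and the estimated correlation alone ended 60 of the 71. Of the 208 list medians 33 changed sign with the scaling, each with a TMM median within 0.08 of 0. Under library totals some lay further off, such as the heat shock genes in MPP at -0.09. A called list was among the 33: ribosomal proteins in MPP, placed higher by camera (adjusted p = 0.0256), went from 0.07 to -0.02 with library totals. At the depth of these libraries, with the same spread of a gene in all groups, the simulated recovery of changes of 0.5 on the log2 scale was at most 32.3%. Depth was not varied by itself.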

Other observations

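Among transcripts annotated on the light strand of the mitochondrial genome, MPP lowered MT-TP, the proline transfer RNA, to 0.131 of DMSO, from 11.9 to 1.55 CPM (edgeR adjusted p = 3e-10). MT-TY and MT-TC, the transfer RNAs for tyrosine and cysteine, had log2 fold changes of -3.21 ± 0.68 and -3.51 ± 0.91 SE (edgeR adjusted p = 0.00176 and 0.0107), while MT-ND6, the protein gene of that strand, was not called (-0.46 ± 0.28, edgeR adjusted p = 0.337). Rotenone lowered MT-TP as well, to 0.533 (edgeR adjusted p = 0.00673). The strand setting of the counts is not given in the sources used here, so these reads can include transcripts of the other strand. The difference between rotenone and MPP was not tested.

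Of 13 Parkinson disease genes, 0 were called in ziram over all genes and 1 fell when adjusted over the list alone, and the list was lower as a group (median log2 fold change -0.17; camera adjusted p = 1.64e-05; adjusted p = 0.0247 with an estimated correlation). With TMM scaling its median was below 0 in every comparison with DMSO, from -0.04 in MS275 to -0.17 in ziram. Camera called the list in 4 of them. Besides ziram these were paraquat (camera adjusted p = 0.0372, and 0.297 with an estimated correlation), 6-HD (0.0214 and 0.223) and methylmercury (median -0.16, and 0.0596 with an estimated correlation). In MS275 the median was 0.02 with RLE size factors. All toxicants share the same DMSO libraries, so the common sign may come from those libraries. Whether the lower list is particular to ziram was not tested.

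Tests chosen after the result was seen were those of metallothionein proportions, of equal induction within groups, of methylmercury profiles, of mitochondrial transcripts moving alike and of distance along the mitochondrial genome; those of HSPA6, of other ribosomal RNA genes and of the hypoxia list were written before it was seen. The first pattern weighed was the few MT1G reads in MS275, paraquat, MPP, rotenone and 6-HD. Reads carried over from the ziram libraries are a candidate source. MT1E, MT2A and MT1M stood to MT1G as in ziram to within 1.03 times (0.979, 1.03 and 1.02). Without rotenone replicate 1, which held 457 of the 884 MT1G reads, they stood at 1.08, 1.2 and 1.26. MT1X at 0.235 (-0.484 to 0.954) and MT1F at -0.706 (-3.11 to 1.7) were left out of the test. With a higher level in DMSO, their expected excess was too small beside its standard error. The interval of MT1X nevertheless lay below the carry-over amount, which goes against carry-over for that gene. HSPA6 was 5.21 times the amount carry-over would bring. The rule written beforehand counted an HSPA6 excess this far above the expected amount against carry-over. That rule is not followed here, because HSPA6 can rise by itself, as in paraquat replicate 2 with 8 HSPA6 and 0 MT1G reads. HSPA6 therefore does not decide on carry-over. Equal induction in every culture was argued against in MS275, paraquat and 6-HD, whose lowest libraries held 0 of the 44.2, 108 and 64.9 reads needed, although the 6-HD figure rests mainly on replicate 3 (59 reads, against 5 in replicate 2). It stayed open in rotenone, where no test was set and the lowest library held 11 of 96.7 reads (0.114, with 457 in replicate 1). In MPP the lowest library held 0.594 of the reads needed. MT1M, MT1X and MT1F stood there at 1.56 (1.08 to 2.03), -0.575 (-1.84 to 0.692) and -3.78 (-7.92 to 0.356) times the carry-over amount. MT1E stood at 1.01 and MT2A at 1.06. These intervals take the spread between cultures from the DMSO libraries only, and hold none for MT1M, with 0 reads in DMSO. They leave out the spread between the MPP cultures. The intervals of MT1X and MT1F lay below the carry-over amount while MT1E and MT2A stood near it, so both explanations stayed open in MPP. In methylmercury MT1X and MT1F were at least 4.84 times the carry-over amount, which argues against carry-over as the main source of their reads. It does not decide on the MT1G reads, since a gene that rises by itself can exceed that amount. MT1E stood there at 2.1 (1.83 to 2.36), MT2A at 2.43 (2.11 to 2.75) and MT1M at 0.552 (0.304 to 0.8) times it. A response of the cells may account for the MT1X and MT1F reads. MT1X and MT1F would have been left out there too by the limit on expected excess, which the methylmercury test did not set.

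The second pattern was the rise of mitochondrial ribosomal RNA in MPP. Weaker depletion of ribosomal RNA cannot be told apart from it, since other ribosomal RNA genes held 11 reads in DMSO and 8 in MPP (0.442 times the share), too few to decide. The rule written beforehand set no minimum of reads and counted a share this low against weaker depletion. A rise of all mitochondrial transcripts alike was argued against by the 3 protein genes that fell. A decline with distance from the heavy strand promoters stayed open (Spearman correlation -0.44 over 14 genes, permutation p = 0.112). No biological explanation was tested.

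The last pattern was the lower hypoxia list in paraquat, MPP and rotenone. Camera also placed the list lower in 6-HD (mean difference -0.15, camera adjusted p = 0.00493, and 0.494 with an estimated correlation). In MS275 the list was not called (mean difference -0.18, camera adjusted p = 0.0704). A single DMSO library as the source of the lower list stayed open. Without DMSO replicate 3 the mean difference went from -0.25 to -0.10 in paraquat. The camera adjusted p without it was 6.69e-05 in paraquat, 0.052 in MPP and 0.041 in rotenone. Leaving out the same library brought the mean difference to 0.01 in 6-HD (camera adjusted p = 0.978) and to -0.02 in MS275. In methylmercury the mean difference went from 0.06 to 0.21 (camera adjusted p = 0.000184). Variation between cultures could also contribute, since the list mean in paraquat lay 1.61 pooled SDs below DMSO, against 1.72 in MPP and 2.47 in rotenone. In ziram the same list lay 2.58 SDs above. No biological explanation was tested.

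For each comparison of 3 against 3 libraries there are 10 splits of the 6, too few for a share under 0.05. The real split called 8136 genes in MS275, 2034 in MPP, 100 in ziram, 1041 in rotenone, 2 in 6-HD, 54 in methylmercury and 2070 in MPP against paraquat, and the highest of the other splits 0 in each, so 1 of 10 was as large. Every other split held libraries of both groups on each side, so differences between the groups counted as spread within a side. Such splits give few calls by construction, so their 0 calls do not measure what chance would give. In paraquat edgeR called 0 in the real split and 0 in the others, so 10 of 10 were as large, with 182 genes at an unadjusted p under 0.05 in the all-library fit and 0 by DESeq2 and limma-voom.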
